A study of Mus musculus with 6 samples.

How the data were processed

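Hepatocyte nuclei of female wild-type C57BL/6J mice were profiled by Smart-seq3xpress, a full-length single-cell RNA-seq method run in plates, at G0 (day 0 of gestation), G14.5 (day 14.5) and P7L (day 7 after birth, lactating). Per the labels, nuclei came either from liver tissue or from a perfused liver, with 1 library for each of the 6 combinations of stage and preparation, and they name no animal. The liver tissue library of each stage is called replicate 1 and the perfusion library replicate 2. Because animals are not named, the p-values below measure only the spread between these 6 libraries.

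The first deposited table holds raw read counts per gene and nucleus, made by the authors with Trimmomatic 0.39, HISAT2 2.1.0 and featureCounts 1.5.3 on GRCm38 (mm10), per the submitters' processing notes, which do not state whether strand was used or which nuclei were removed. It has 40824 genes and 1567 nuclei, and its counts are reads, not molecules. The second deposited table holds TPM-like values of the authors: each count was divided by a length per gene and each nucleus scaled to 100000, with Alb, Apoa2 and Fabp1 left out of the sum, as worked out from the values themselves. Totals with these 3 genes ran from 100214 to 134901. The 92 rows of ERCC spike-in controls held 0 reads, and the tables have no mitochondrial genes.

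Reads were summed over the nuclei of each library, giving 226030591 reads for G0 liver tissue and 248183987 for G0 perfusion. The G14.5 libraries held 264739495 (liver tissue) and 379767336 (perfusion), and the P7L libraries 258327734 and 327263106. All 1567 nuclei were used and no doublet caller was run. A gene was tested if it passed filterByExpr by stage and had at least 1 read in at least 5% of the nuclei of at least 2 libraries, which left 15015 genes. The edgeR quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) was fitted to all 6 libraries with terms for stage and preparation, TMM scaling and robust moderation. This left 2 residual degrees of freedom, with a prior of 5.13 and a common coefficient of variation of 0.357. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Normalised read counts are given as CPM, read counts scaled to the TMM library size, and log2 fold changes with their standard error (SE). Intervals are taken over the nuclei of 1 library, so they cover counting error only and not the spread between libraries or animals. Reads without molecular identifiers are not independent molecules. The model has no degrees of freedom left for a test of stage by preparation.

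There were 24 lists of liver gene groups and 10 lists of cell type markers, fixed together with the tests and the alternatives before the data were examined. Of these, 31 had at least 5 tested members and were tested with camera (limma 3.58.1) on voom log2 CPM at a preset correlation between genes of 0.01, and again with the correlation estimated per list. The self-contained test fry was run beside it. Named genes follow a rule set in advance. For each stage comparison it takes up to 10 higher and 10 lower genes with the largest change among the called genes, the same direction in both preparations, at least 20 CPM in both libraries of the higher stage and reads in at least 20% of their nuclei, without gene models whose symbol begins with Gm and a digit or ends in Rik. Gene models with clone names were not left out. It adds up to 4 members of each list with the smallest p. For the preparation comparison, where fewer than 5 genes passed, it names the 10 with the smallest p. Some genes that the rule takes are not reported here. Socs2 at G14.5 against G0, Sult2a1, Cyp3a11 and Abcb11 were named to complete a count. They, Dnajb1, Hsph1, Hspb1, Lyz2, Clec4f and the genes in the plot of preparations were chosen after their values were seen.

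For the share of cycling nuclei, each nucleus was thinned to 250000 reads, which left out 35 shallower nuclei, and counted as cycling with reads of at least 3 of 10 cycling genes. The zonation index of a nucleus is its reads of pericentral genes divided by its reads of pericentral and periportal genes together. Shares have exact Clopper-Pearson 95% intervals and medians have exact binomial 95% intervals, both over nuclei.

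The tests were checked on simulated counts for the 15015 genes with 200 changed genes per stage or preparation. At 4-fold, edgeR recovered 62.1% of the changed genes for G14.5 against G0, 58.2% for P7L against G0, 65.4% for P7L against G14.5 and 65.7% for the preparations. At 1.5-fold it recovered 4.5%, 3.0%, 3.7% and 15.2%. Its false calls numbered 2 of 60, 6 of 61, 7 of 135 and 4 of 84, against 85 of 163, 74 of 145, 85 of 245 and 61 of 162 for DESeq2 1.42.0. In 40 simulated sets with no change, edgeR called on average 0.925, 0.5, 0.875 and 0.8 genes.

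Alternatives were RLE size factors, other filters, no term for the other factor, thinned nuclei, limma-voom, DESeq2, limma on the authors' mean values with pseudocounts of 1 and 0.1, and each library left out in turn. Scaling by library size alone and removal of a trend with gene length were added after the data had been seen. Gene positions and lengths come from GENCODE M21 on GRCm38 and were found for 14130 of the tested genes. Other steps used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.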

Results

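The data are read counts of 1567 hepatocyte nuclei in 6 libraries, 2 at each of the stages G0, G14.5 and P7L, 1 from liver tissue and 1 from perfusion. The series follows the states of maternal hepatocytes through gestation and lactation. The libraries held 252 (G0 liver tissue), 184 (G0 perfusion), 224 (G14.5 liver tissue), 301 (G14.5 perfusion), 308 (P7L liver tissue) and 298 (P7L perfusion) nuclei. Median reads per nucleus ran from 731494 in P7L liver tissue to 1191576 in G14.5 perfusion. The median number of genes per nucleus, after thinning to 250000 reads, was 5650 and 5386 at G0, 6002 and 6037 at G14.5 and 6701 and 6753 at P7L, liver tissue first. Reads of the hepatocyte markers made up 1.54% to 1.84% of all reads, and no nucleus had over 1% of its reads in the markers of any other cell type. This limit is coarse and cannot show that the nuclei are pure. In G0 perfusion the hepatocyte markers themselves passed it in only 152 of 184 nuclei.

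The comparison of G14.5 with G0 asks how hepatocytes change by mid to late gestation. The receptors of growth hormone and prolactin rose. Ghr went from 6636 and 6470 CPM at G0 to 27770 and 29180 CPM at G14.5 (log2 fold change 2.12 ± 0.10 SE, edgeR adjusted p = 9.53e-05), with n = 2 libraries per stage here and below. Prlr went from 1887 and 1445 to 10940 and 13120 CPM (2.86 ± 0.16, adjusted p = 0.000176). Vwf, which encodes the clotting protein von Willebrand factor, rose from 0.23 and 0.37 CPM to 115 and 117 CPM (8.64 ± 0.33, adjusted p = 4.52e-05), with reads in 84.8% and 89.0% of nuclei at G14.5. Abcc3, an export pump for conjugated bile acids, went the other way, from 213 and 237 CPM to 6.65 and 5.79 CPM (-5.18 ± 0.18, adjusted p = 2.65e-05). So did Hamp, the gene of the iron hormone hepcidin, from 1874 and 2397 CPM to 205 and 134 CPM (-3.68 ± 0.23). On GRCm38, Vwf lies on chromosome 6 from 125546774 to 125686679 and Abcc3 on chromosome 11 from 94343295 to 94392997.

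Of 15015 genes, edgeR called 1793 between G14.5 and G0, 1040 higher and 753 lower. Of all tested genes, 68.1% had the same direction in both preparations. Leading higher genes were Sult4a1 (log2 fold change 10.02), Vwf, Sorcs3 (7.79), Dnah11 (7.03), Efhb (6.68), Stk33 (6.60), Colgalt2 (6.54), Crybb3 (6.33) and Nedd9 (6.33). The leading lower genes were Sult2a3 (-7.87), Nxph1 (-5.75), Rgs16 (-5.32), Abcc3, Mfsd2a (-4.47), Ildr2 (-3.96), Nxpe2 (-3.72), Hamp, Rad51b (-3.48) and C9 (-3.47). Reads of Sult2a3 and Serpina1e can be shared with near-identical copies, and Dnah11 and Nxpe2 each overlap a protein-coding gene on the other strand, so their counts are uncertain. Without the G14.5 liver tissue library the count was 661 and without the G14.5 perfusion library 815, whereas DESeq2 called 3429. Scaled by library size alone, which put the median of all genes at -0.13, 891 genes were higher and 1101 lower, and on the authors' values 557 and 571 with a pseudocount of 1 and 837 and 890 with 0.1.

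Some genes of cholesterol synthesis and uptake rose at G14.5: 9 of 21 tested members were higher and 0 lower (13 and 0 adjusted over the list alone). Among them were Fdps (log2 fold change 2.63 ± 0.17), Hmgcs1 (2.56 ± 0.25) and Fdft1 (1.51 ± 0.19). Camera gave an adjusted p = 2.67e-07, and an adjusted p = 0.545 with an estimated correlation. Of 21 cell cycle genes 5 rose and 0 fell (11 and 0 adjusted over the list alone), such as Mki67 (5.07 ± 0.72) and Top2a (3.72 ± 0.44). The list had an adjusted p = 7.34e-06 (adjusted p = 0.545 with an estimated correlation). In the unfolded protein response, 7 of 17 genes rose and 0 fell (9 and 0 adjusted over the list alone), with the chaperone-related genes Creld2 (2.65 ± 0.28) and Manf (2.50 ± 0.27) in front. Its adjusted p was 0.000124 (adjusted p = 0.545 with an estimated correlation). Bile acid synthesis had 5 of 12 genes higher and 0 lower (6 and 0 adjusted over the list alone), including Cyp7a1, the rate-limiting enzyme (2.01 ± 0.25), and Cyp8b1, which directs synthesis to cholic acid (3.08 ± 0.27). That list had an adjusted p = 0.00396 (adjusted p = 0.602 with an estimated correlation). The acute phase list was split, with 7 of 23 genes higher, such as Cp (2.37 ± 0.12) and Itih4 (1.61 ± 0.17), and 3 lower, including Hamp and Orm3 (-2.54 ± 0.30). Adjusted over the list alone, 12 were higher and 3 lower, and camera gave an adjusted p = 0.0184 upward (adjusted p = 0.602 with an estimated correlation).

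Among the lists that were lower at G14.5, amino acid catabolism and the urea cycle had 13 of 20 genes lower and 2 higher (15 and 2 adjusted over the list alone), with Prodh at -2.75 ± 0.21, Aass at -1.32 ± 0.12 and Tat at 1.56 ± 0.15. The list had an adjusted p = 4.51e-06 (adjusted p = 0.602 with an estimated correlation). Pericentral genes, expressed around the central vein, had 7 of 17 lower and 0 higher (9 and 1 adjusted over the list alone), led by Cyp2e1 (-1.78 ± 0.12) and Cyp2a5 (-2.09 ± 0.15). Camera gave them an adjusted p = 0.00186 (adjusted p = 0.602 with an estimated correlation). Periportal genes, from the other end of the lobule, had 7 of 18 lower and 2 higher (8 and 4 adjusted over the list alone), such as Hsd17b13 (-2.13 ± 0.16) and Cdh1 (1.96 ± 0.31). They had an adjusted p = 0.0273 (adjusted p = 0.627 with an estimated correlation). The median of the periportal list was -1.029 in liver tissue and -0.159 in perfusion, and that of the pericentral list -0.385 and -1.03. Xenobiotic metabolism had 8 of 18 genes lower and 3 higher (11 and 3 adjusted over the list alone), with Gstt1 at -2.10 ± 0.22 and Gstm3 at 3.27 ± 0.47. Bile acid transport had 5 of 11 lower and 0 higher (5 and 2 adjusted over the list alone), with the uptake carriers Slco1a4 (-3.06 ± 0.14) and Slco1b2 (-1.87 ± 0.13) beside Abcc3. Both had an adjusted p = 0.00345 (adjusted p = 0.602 and 0.557 with an estimated correlation). Gluconeogenesis and glycolysis had 4 of 16 genes lower and 0 higher (8 and 2 adjusted over the list alone), including Khk (-1.37 ± 0.22). Its median was -0.695 in liver tissue and -0.162 in perfusion. Oxidative phosphorylation had 2 of 16 lower, Sdhb (-0.89 ± 0.21) and Atp5b (-0.73 ± 0.18), and 0 higher (2 and 0 adjusted over the list alone). Immediate early and heat shock genes had 6 of 18 lower and 2 higher (9 and 2 adjusted over the list alone), with Egr1 at -2.41 ± 0.32 and Myc at 3.71 ± 0.65. These last lists each had an adjusted p = 0.00396 (adjusted p = 0.627 for the first and 0.602 for the others with an estimated correlation).

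Lists that did not pass camera at G14.5 against G0 held strong single changes. Fatty acid and triglyceride synthesis had 7 of 18 genes higher and 4 lower (the same counts adjusted over the list alone), with Pnpla3, a lipid droplet protein, at 4.62 ± 0.19 and Fads2 at 2.36 ± 0.18 (list adjusted p = 0.162). Prolactin and growth hormone signalling had 4 of 13 higher, Ghr, Prlr, Igfbp2 (1.05 ± 0.18) and Socs2 (1.34 ± 0.26), and 1 lower, Igf1 (-0.92 ± 0.17), at adjusted p = 0.0733. The circadian clock had 2 of 16 higher, among them Arntl (1.96 ± 0.27), and 6 lower, among them Hlf (-1.47 ± 0.17), at adjusted p = 0.0586. Fatty acid oxidation had 4 of 21 higher, such as Cd36 (1.45 ± 0.21), and 5 lower, such as Acaa1b (-1.23 ± 0.12), at adjusted p = 0.524. Female-biased genes had 3 of 17 higher and 4 lower, with A1bg at 2.07 ± 0.26 and Cyp2b13 at -2.71 ± 0.17 (adjusted p = 0.304). Male-biased genes had 3 of 11 higher and 1 lower, with Serpina1e at 5.48 ± 0.22 and Nox4 at -2.19 ± 0.25 (adjusted p = 0.25). Plasma proteins had 3 of 19 higher, among them Alb (1.25 ± 0.13) and Serpinc1 (1.59 ± 0.12), and 3 lower, among them Ttr (-1.06 ± 0.19), at adjusted p = 0.691. Hepatocyte transcription factors had 1 of 19 higher, Foxa3 (1.06 ± 0.24), and 1 lower, at adjusted p = 0.0733. Fetal liver genes had 1 of 5 higher, Peg3 (3.82 ± 0.18), and 1 lower, Sox9 (-2.18 ± 0.53), at adjusted p = 0.146. Of 14 interferon response genes and 16 ribosome biogenesis genes edgeR called 0, with adjusted p = 0.331 and 0.414 for the lists. Adjusted over the list alone, 9 fatty acid oxidation genes were higher and 6 lower, 4 and 9 of the clock, and 6 and 4 plasma proteins. Female-biased genes then had 3 and 5, male-biased genes 5 and 2, transcription factors 2 and 5, and fetal liver genes 2 and 1.

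**Figure D1:**
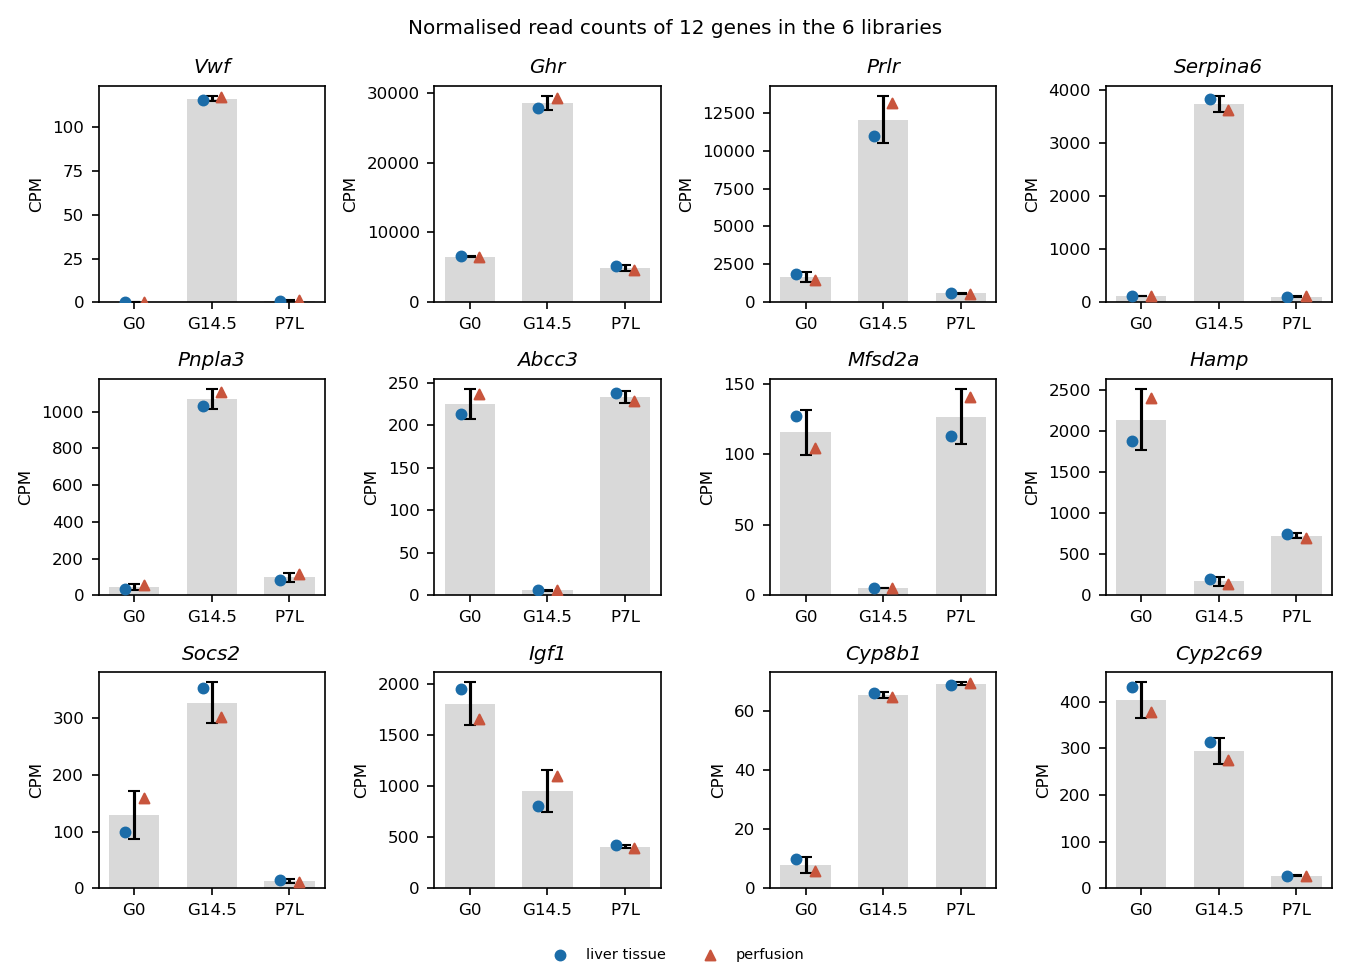
Normalised read counts (CPM, vertical axes from 0) of 12 genes by stage. Points are the single libraries (circles liver tissue, triangles perfusion), bars their means and error bars the SD of 2 libraries. Vwf, Ghr, Prlr, Serpina6 and Pnpla3 were highest and Abcc3, Mfsd2a and Hamp lowest at G14.5 in both preparations, and Igf1 and Cyp2c69 were lowest at P7L.

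The comparison of P7L with G0 asks which differences are present in lactation. Igf1, the main growth factor released by the liver, fell from 1952 and 1654 CPM at G0 to 421 and 397 CPM (-2.14 ± 0.18, edgeR adjusted p = 0.00373). Socs2 and Cish, feedback inhibitors induced by growth hormone and prolactin, fell too (-3.29 ± 0.28 and -3.63 ± 0.48), as did Prlr (-1.49 ± 0.15). Cyp8b1 rose from 9.91 and 5.92 CPM to 69.1 and 69.7 CPM (3.16 ± 0.27, adjusted p = 0.00416) and Cyp7a1 by 1.79 ± 0.25. The cytochrome P450 gene Cyp2c69, whose reads can be shared with near-identical copies, fell from 430 and 377 CPM to 27.4 and 25.9 CPM (-3.92 ± 0.14, adjusted p = 0.000196).

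In all, edgeR called 438 genes between P7L and G0, 234 higher and 204 lower, and 66.1% of all tested genes had the same direction in both preparations. The other leading higher genes were 2 gene models with clone names (log2 fold changes 4.97 and 3.24), Chrna4 (4.06), Hcls1 (3.47), Dntt (2.65), Pvt1 (2.57), Slc24a3 (2.40), Capn11 (2.39) and Cyp2d40 (2.36). The other leading lower genes were Sult2a3 (-3.55), Egr1 (-3.15), Wsb1 (-2.66), Actb (-2.25), Cyp2j9 (-2.22), Slc22a27 (-2.21) and Adamts6 (-2.13). The count was 75 without the P7L liver tissue library and 46 without the P7L perfusion library, 92 with filterByExpr alone, 227 with no filter, 4 and 205 on the authors' values with pseudocounts of 1 and 0.1, and 1901 by DESeq2. Only Cyp2c69, Sult2a3 and Wsb1, of 68 named genes, kept their call in every alternative, and scaling by library size alone gave 309 higher and 172 lower genes.

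Camera at the preset correlation called both lipid synthesis lists higher at P7L than at G0, while edgeR called a minority of their members. Cholesterol synthesis and uptake had 6 of 21 genes higher, such as Fdps (2.05 ± 0.17), and 1 lower, Insig1 (-0.92 ± 0.11), with 13 and 1 adjusted over the list alone. Fatty acid and triglyceride synthesis had 7 of 18 higher and 0 lower, such as Thrsp (1.22 ± 0.14) and Acss2 (1.04 ± 0.17), with 12 and 1 adjusted over the list alone. Camera gave adjusted p = 6.25e-07 and 5.62e-06 (adjusted p = 0.518 for both with an estimated correlation). The cell cycle list had 3 of 21 higher, Mcm2 (4.79 ± 0.81), Top2a (2.42 ± 0.42) and Mki67 (3.89 ± 0.69), and 0 lower (8 and 1 adjusted over the list alone). Its adjusted p was 2.04e-05 (adjusted p = 0.518 with an estimated correlation). Bile acid synthesis had 5 of 12 higher and 0 lower (8 and 0 adjusted over the list alone), at adjusted p = 0.000413 (adjusted p = 0.518 with an estimated correlation). Amino acid catabolism and the urea cycle had 6 of 20 higher and 0 lower (9 and 2 adjusted over the list alone), including the urea cycle enzymes Ass1 (0.89 ± 0.13) and Asl (1.04 ± 0.16). Its adjusted p was 0.0179 (adjusted p = 0.588 with an estimated correlation). The median of this list was 0.004 in the liver tissue libraries and 0.352 in perfusion, so it hardly moved in liver tissue.

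Prolactin and growth hormone signalling had 4 of 13 genes lower at P7L than at G0, the named Igf1, Socs2, Cish and Prlr, and 0 higher (9 and 1 adjusted over the list alone), at adjusted p = 5.53e-05. Female-biased liver genes had 7 of 17 lower, among them Cyp2b13 (-1.98 ± 0.17) and Cux2 (-1.67 ± 0.21), and 1 higher, Sult2a1 (0.69 ± 0.12), with 9 and 2 adjusted over the list alone (adjusted p = 3.78e-05). Hepatocyte transcription factors and nuclear receptors had 2 of 19 lower, Esr1 (-0.81 ± 0.13) and Hnf4a (-0.73 ± 0.13), and 0 higher (7 and 0 adjusted over the list alone), at adjusted p = 7.17e-05. The acute phase list had 6 of 23 lower, such as C3 (-1.69 ± 0.14) and Hamp (-1.57 ± 0.21), and 0 higher (10 and 1 adjusted over the list alone), at adjusted p = 0.00032. Each of these had an adjusted p = 0.518 with an estimated correlation. The hepatocyte markers had 3 of 10 lower, Cyp2e1 (-1.35 ± 0.12), Ahsg (-0.91 ± 0.12) and Hnf4a, and 1 higher, Alb (0.97 ± 0.13), with 6 and 1 adjusted over the list alone (adjusted p = 0.00594). Their summed share of reads did not fall, at 1.73% and 1.84% at P7L and 1.63% and 1.54% at G0, liver tissue first. Immediate early and heat shock genes had 3 of 18 lower, Egr1, Fos (-4.76 ± 0.91) and Dusp1 (-1.28 ± 0.25), and 0 higher, with 5 and 0 adjusted over the list alone (adjusted p = 0.0209). The hepatocyte and immediate early lists both had an adjusted p = 0.521 with an estimated correlation. Of 17 unfolded protein response genes edgeR called 0, with 1 higher and 3 lower adjusted over the list alone, and the list had an adjusted p = 0.0478 downward (adjusted p = 0.518 with an estimated correlation).

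P7L was then compared with G14.5, to follow the step from gestation to lactation. Serpina6, the gene of corticosteroid-binding globulin, had 3834 and 3625 CPM at G14.5 and 103 and 113 CPM at P7L (-5.11 ± 0.13, edgeR adjusted p = 1.51e-05), next to 121 and 118 CPM at G0. Prlr fell by 4.34 ± 0.17 and Ghr by 2.53 ± 0.10 on the log2 scale (adjusted p = 5.51e-05 for both), to 605 and 583 CPM for Prlr. Abcc3 rose by 5.23 ± 0.18 (adjusted p = 3.62e-05) to 238 and 229 CPM, and Mfsd2a, a carrier of lysophospholipids, by 4.61 ± 0.23.

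Between P7L and G14.5 edgeR called 1390 genes, 630 higher and 760 lower, and 70.6% of all tested genes had the same direction in both preparations. The other leading higher genes were Rgs16 (log2 fold change 5.99), Mme (4.85), Nxph1 (4.40), Hcls1 (4.27), Capn11 (4.15), Ak4 (4.07), Prex2 (4.04) and C9 (3.76). The other leading lower genes were Crybb3 (-8.29), Vwf (-6.76), Clec2h (-6.75), Efhb (-6.39), Dnah11 (-5.56), Nckap5 (-5.52), Adcy1 (-5.52) and Sult4a1 (-5.31). The count was 581 and 638 without the G14.5 liver tissue or perfusion library, 505 and 450 without those of P7L, 2289 and 2350 without those of G0, and 2631 by DESeq2. Scaling by library size alone, with the median of all genes at 0.20, gave 1048 higher and 551 lower genes, and the authors' values gave 557 and 442 with a pseudocount of 1 and 749 and 549 with 0.1.

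Amino acid catabolism and the urea cycle had 13 of 20 genes higher at P7L than at G14.5 and 0 lower (16 and 1 adjusted over the list alone), such as Gpt2 (1.62 ± 0.11), Prodh (2.57 ± 0.21) and Sds (2.29 ± 0.22). This list had an adjusted p = 7.56e-12 (adjusted p = 0.63 with an estimated correlation). Gluconeogenesis and glycolysis had 7 of 16 higher, such as Khk (1.73 ± 0.23), and 1 lower, G6pc (-1.21 ± 0.20), with 9 and 1 adjusted over the list alone (adjusted p = 7.27e-05). Pericentral genes had 3 of 17 higher, Cyp2a5 (2.09 ± 0.15), Cyp1a2 (1.49 ± 0.21) and Lgr5 (1.71 ± 0.42), and 0 lower, with 8 and 1 (adjusted p = 0.000265). Oxidative phosphorylation had 1 of 16 higher, Sdhb (1.41 ± 0.21), and 0 lower, with 1 and 0 (adjusted p = 0.00122). The circadian clock had 9 of 16 higher, such as Dbp (2.69 ± 0.30), and 4 lower, such as Arntl (-2.41 ± 0.27) and Npas2 (-3.95 ± 0.49), with 10 and 4 (adjusted p = 0.0116). For each of these last 4 lists the adjusted p was 0.653 with an estimated correlation. Xenobiotic metabolism had 7 of 18 higher, such as Nr1i3 (1.66 ± 0.18), and 1 lower, Cyp3a11 (-1.38 ± 0.22), with 10 and 2 adjusted over the list alone (adjusted p = 0.00088). Bile acid transport had 4 of 11 higher, Abcc3, Slco1a4 (3.12 ± 0.14), Slco1b2 (1.51 ± 0.12) and Slc10a1 (1.43 ± 0.12), and 1 lower, the bile salt export pump Abcb11 (-1.07 ± 0.11), with 5 and 2 (adjusted p = 0.0168). Both had an adjusted p = 0.63 with an estimated correlation. Periportal genes had 6 of 18 higher, such as Etnppl (3.34 ± 0.38), and 3 lower (10 and 3 adjusted over the list alone), at adjusted p = 0.00222 (adjusted p = 0.687 with an estimated correlation).

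The unfolded protein response had 9 of 17 genes lower at P7L than at G14.5, such as Manf (-2.97 ± 0.28) and Hspa5 (-2.07 ± 0.22), and 0 higher (11 and 1 adjusted over the list alone), at adjusted p = 2.6e-07. Prolactin and growth hormone signalling had 6 of 13 lower, such as Socs2 (-4.63 ± 0.30) and Cish (-4.08 ± 0.49), and 0 higher (8 and 0 adjusted over the list alone), at adjusted p = 1.25e-06. Both had an adjusted p = 0.61 with an estimated correlation. The acute phase list had 10 of 23 lower, such as Cp (-3.19 ± 0.12) and Itih4 (-2.70 ± 0.17), and 2 higher (10 and 2 adjusted over the list alone), at adjusted p = 7.28e-06 (adjusted p = 0.63 with an estimated correlation). The cell cycle list had 0 of 21 genes called by edgeR (median -0.37, adjusted p = 0.255), and cholesterol synthesis and uptake 2 of 21 higher and 3 lower (adjusted p = 0.358). Fatty acid and triglyceride synthesis had 6 of 18 higher, such as Scd1 (2.13 ± 0.24), and 6 lower, such as Pnpla3 (-3.46 ± 0.18), at adjusted p = 0.335.

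**Figure D2:**
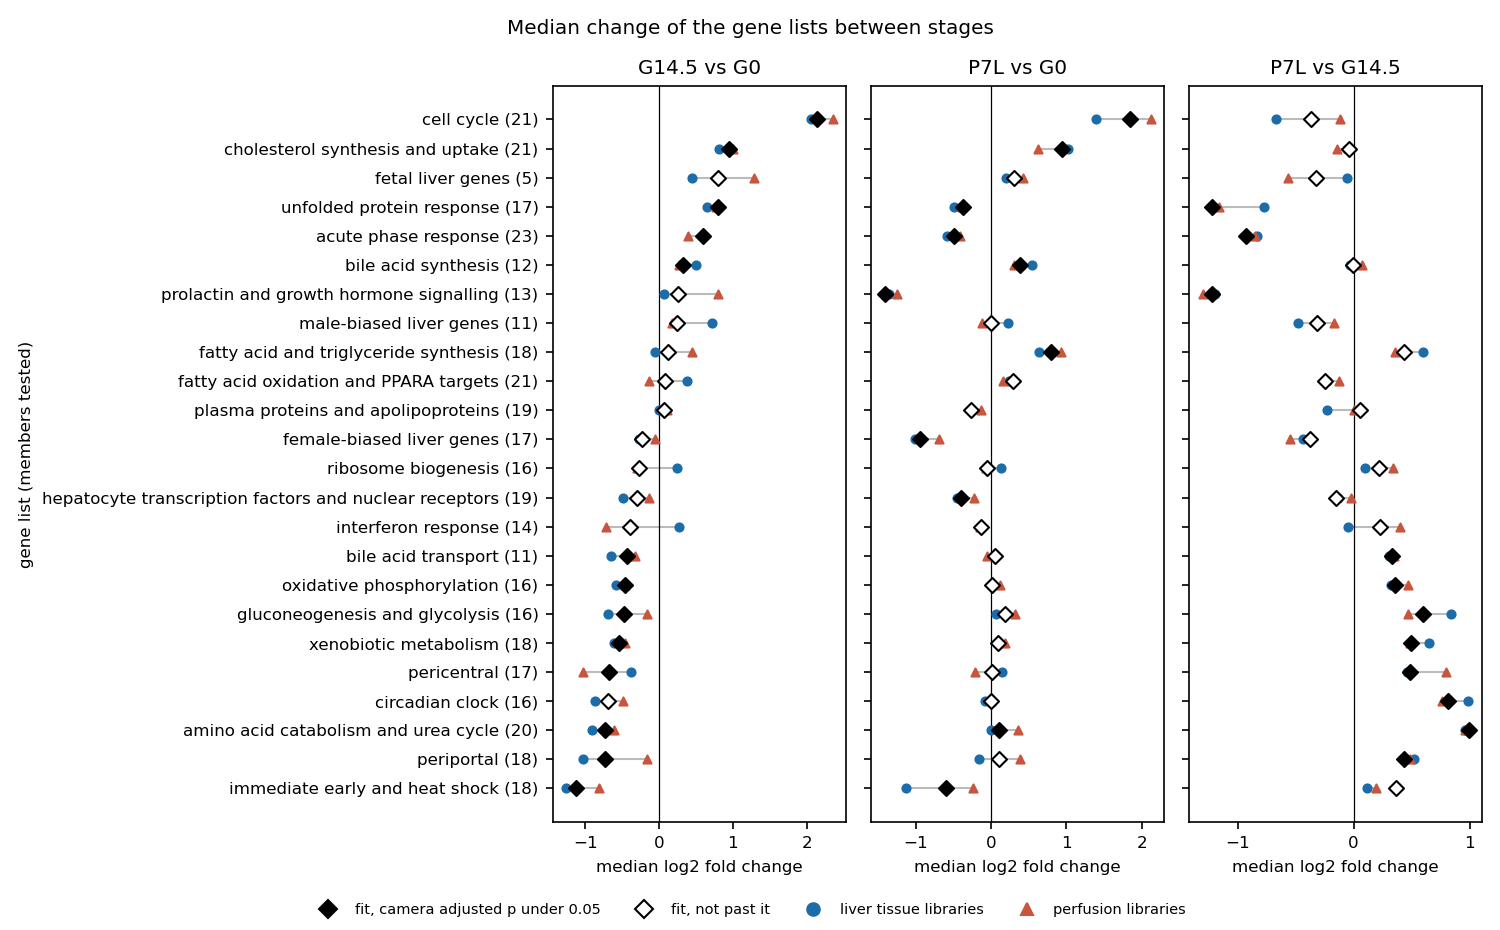
Median log2 fold change (horizontal axes) of the tested members of 24 gene lists in the 3 stage comparisons. Diamonds are the medians of the fit, filled where the camera adjusted p was under 0.05, and circles and triangles the medians in the liver tissue and perfusion libraries. Amino acid catabolism lies at -0.73 at G14.5 against G0 and at 0.99 at P7L against G14.5.

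Across the lists, camera called 13, 12 and 11 of 31 in G14.5 against G0, P7L against G0 and P7L against G14.5, and 0 in each with an estimated correlation, where 2 lists had an unadjusted p under 0.05 each time. The fry test called 4, 2 and 5. The median of every called list kept its sign under each scaling, and its median, mean and test had the same sign. Among the other lists, sign differed between these measures for the erythroid and stellate lists (G14.5 against G0), for bile acid transport, pericentral, circadian clock and ribosome biogenesis genes (P7L against G0) and for the plasma protein and cholangiocyte lists (P7L against G14.5). Of the non-hepatocyte marker lists, macrophage, endothelial, stellate, cholangiocyte, B cell and erythroid, camera called none in a stage comparison, with adjusted p from 0.138 to 0.983, and fry called the endothelial list lower at P7L than at G0 (adjusted p = 0.0464). Dnase1l3, of the endothelial list (1.68 ± 0.37), and Sox9, of the cholangiocyte list, were the only members that edgeR called in these lists. The T and NK cell list (4 tested members), the neutrophil list (2) and the mesothelial list (1) were too small to test.

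In both comparisons with G0, 216 genes were called in the same direction, 149 higher and 67 lower, and 36 in opposite directions. Cyp8b1, Cyp7a1, Fdps and Mki67 were higher at both G14.5 and P7L, and Sult2a3, Cyp2e1, Igf1 and Egr1 lower at both. Independent lists would share 16.2 higher and 10.2 lower genes and hold 25.9 in opposite directions. Simulated stages with no change shared 0.025 genes on average. Only 0.925 and 0.5 genes were called there, so this cannot show how far shared G0 libraries raise the overlap of longer lists. Fold changes correlated across genes (which are not independent replicates) at r = 0.564 against 0.501 simulated from the shared G0 libraries alone, with covariances of 0.633 and 0.158, a difference of 0.475. The G0 libraries cannot be split with 2 in each part, so part of the excess may come from them. Fold changes between single libraries that shared a G0 library correlated at 0.57 and 0.614 (covariances 0.777 and 0.922). With separate G0 libraries they correlated at 0.258 and 0.247 (covariances 0.383 and 0.341), and these pairs also differed in preparation. The count was 338 without the G0 liver tissue library, 121 without that of G14.5, 51 and 35 without the P7L liver tissue or perfusion library, and 947 by DESeq2. It was 54 with filterByExpr alone, 121 with no filter, and 2 and 116 on the authors' values with pseudocounts of 1 and 0.1.

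The share of nuclei with reads of at least 3 of 10 cycling genes, thinned to equal reads, was 0.844% (2 of 237, 95% interval 0.102% to 3.02%) and 0.552% (1 of 181, 0.014% to 3.04%) at G0, for liver tissue and perfusion. At G14.5 it was 9.38% (21 of 224, 5.90% to 13.97%) and 3.00% (9 of 300, 1.38% to 5.62%), and at P7L 4.42% (13 of 294, 2.38% to 7.44%) and 3.72% (11 of 296, 1.87% to 6.55%). The intervals of the G14.5 liver tissue library and both G0 libraries did not overlap, and those of the perfusion libraries overlapped between all stages in this setting. Genes per nucleus still differed after thinning, with medians from 5386 in G0 perfusion to 6753 in P7L perfusion, and the shares were not corrected for this. Without thinning the shares were 2.78% and 5.43% at G0, 21.9% and 13.6% at G14.5 and 13.96% and 13.8% at P7L, and neither preparation's G0 interval overlapped those of its later stages. The median zonation index was 0.302 (95% interval 0.23 to 0.362) and 0.313 (0.186 to 0.395) at G0, 0.211 (0.153 to 0.303) and 0.109 (0.084 to 0.134) at G14.5, and 0.208 (0.168 to 0.261) and 0.08 (0.061 to 0.119) at P7L, liver tissue first. It was lower than at G0 in both preparations at both later stages, but in liver tissue the intervals of both later stages overlapped that of G0. Without Cyp2e1, Glul, Cyp2f2 and Pck1, liver tissue had 0.169 at G0, 0.199 at G14.5 and 0.164 at P7L, with no fall at G14.5, and perfusion 0.161, 0.1 and 0.076, where the intervals of G0 and G14.5 overlapped. No test of either measure between the libraries was made.

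**Figure D3:**
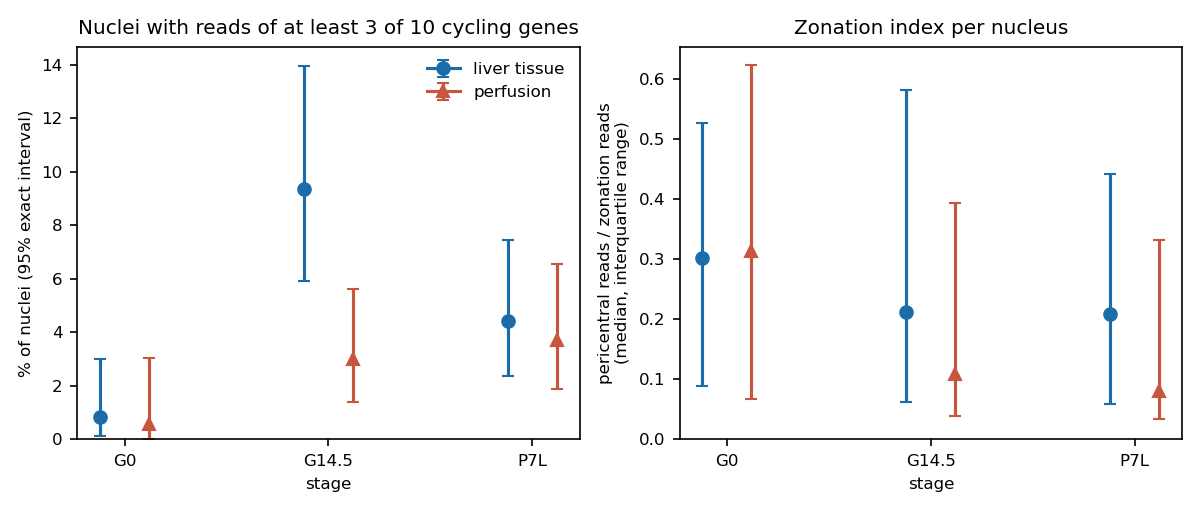
Left, share of nuclei (%) with reads of at least 3 of 10 cycling genes after thinning, with exact 95% intervals. Right, zonation index per nucleus (pericentral reads over pericentral and periportal reads), median and interquartile range. Circles are liver tissue and triangles perfusion libraries, and the G14.5 liver tissue library has the highest cycling share, 9.38%.

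The preparations were compared across the 3 stages (n = 3 libraries each). Most genes of the immediate early and heat shock list lay higher in perfusion libraries, with positive log2 fold changes for 16 of 18 members and a median of 0.73. Among them were Dusp1 (1.46 ± 0.20, edgeR adjusted p = 0.444) and Zfp36 (1.12 ± 0.18, adjusted p = 0.624). The others were the heat shock genes Dnajb1 (-0.352) and Hsph1 (-0.086), and the heat shock gene Hspb1 (1.416) was negative at G14.5 (-0.839). Globin genes lay lower: Hbb-bs had 3.62, 4.55 and 2.99 CPM in liver tissue and 0.16, 0.42 and 0.15 CPM in perfusion at G0, G14.5 and P7L (-4.09 ± 0.55, adjusted p = 0.444). All 11 tested Kupffer cell and macrophage markers had negative fold changes, such as Lyz2 (-1.87 ± 0.50) and Clec4f (-1.32 ± 0.42), which were chosen after their values were seen. None of these single genes passed the threshold. Of 15015 genes edgeR called 0, with 707 at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 87. These 707 are fewer than unchanged genes alone would give at that threshold. The other splits of the libraries with 1 library per stage in each part gave 479, 457 and 899. Besides Dusp1, Zfp36 and Hbb-bs, the genes with the smallest p included Mt1 (0.82), Thrsp (0.91), Slpi (4.13), Wfdc17 (-4.11), Klf10 (0.88) and Bhlhe40 (0.72).

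Camera called 12 of 31 lists between the preparations, 7 higher and 5 lower in perfusion. The immediate early list (5 higher and 0 lower adjusted over the list alone) and the Kupffer cell list (0 and 0) both had an adjusted p = 4.89e-07, and the erythroid list (0 and 4) an adjusted p = 6.51e-07 at a median of -3.26. In the erythroid list only the globin genes were lower, and the other tested members, Slc4a1 (0.001) and Klf1 (0.367), were not. Cell cycle genes had negative values for 18 of 21 members (median -0.67, adjusted p = 4.88e-05, 0 called adjusted over the list alone), and the B and plasma cell list had a median of -0.54 (adjusted p = 0.00137, 0 and 1). With an estimated correlation each of these lists had an adjusted p = 0.566. Lists with positive medians were amino acid catabolism (0.21, adjusted p = 1.13e-06), fatty acid and triglyceride synthesis (0.19, 2.82e-05), gluconeogenesis and glycolysis (0.22, 0.000147), circadian clock (0.14, 0.00647) and the acute phase response (0.08, 0.0382), and stellate markers had a negative one (-0.62, 0.0339). Each of these had an adjusted p = 0.577 with an estimated correlation. Adjusted over the list alone, 2 genes of fatty acid synthesis, 2 of gluconeogenesis and 1 of the clock list were higher and 0 of the others. Periportal genes had a median of 0.24 (0 called adjusted over the list alone, adjusted p = 0.000494, and adjusted p = 0.605 with an estimated correlation). With an estimated correlation 0 lists were called and 2 had an unadjusted p under 0.05, and fry called 0. Sign differed between median, mean and test for fatty acid oxidation, male-biased, xenobiotic and bile acid transport genes, none of them called.

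**Figure D4:**
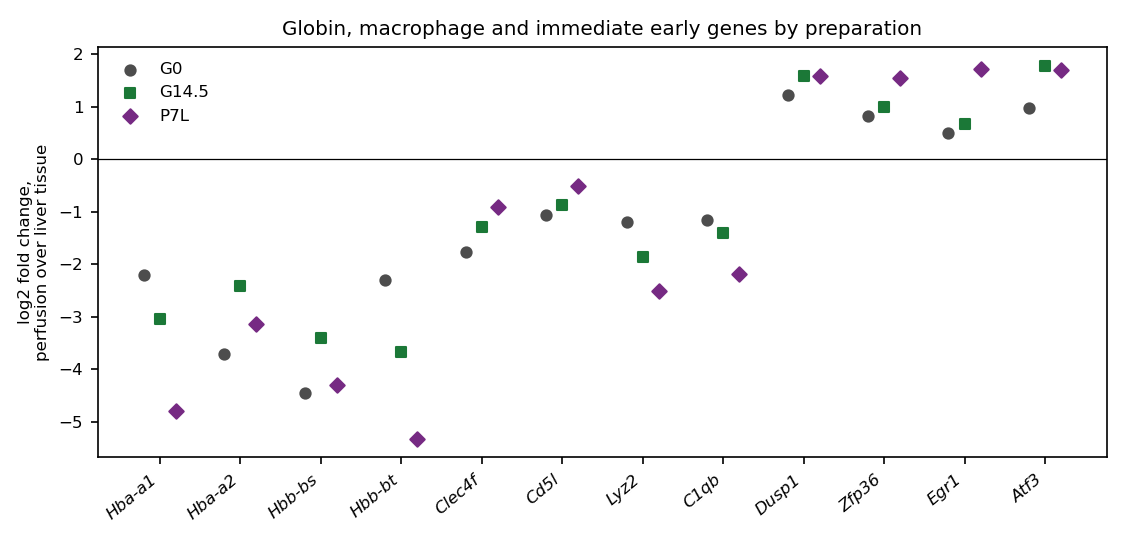
Log2 fold change of perfusion over liver tissue libraries (vertical axis) at each stage for 12 globin, macrophage and immediate early genes. Each point is the difference of 2 libraries. The 12 genes, below 0 for globin and macrophage genes and above 0 for immediate early genes, were chosen after their values were seen, as were the exceptions named here. Other members of these lists differ in sign between stages, such as Junb (-0.723), Jund (-0.893), C1qa (0.975) and Csf1r (0.544) at G0 and Cd68 (1.166) at P7L. None of the 12 passed the edgeR threshold.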

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

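All tests in this part were chosen only after the results were seen, and both patterns weighed here come from the same data as their tests.

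Vwf, usually a gene of endothelial cells, stood at 116 ± 1.34 CPM (SD, n = 2) at G14.5 and 0.3 ± 0.1 CPM at G0. RNA from endothelial cells would raise their other markers as well, but the summed CPM of 10 of them went from 43.8 ± 9.04 to 47.8 ± 14.8, a rise of 4.08, with Dnase1l3 (27.1 CPM) and Stab2 (6.63 CPM) the highest at G14.5. Dnase1l3 itself rose, from 8.77 CPM at G0. Of the 10 markers, 4 had positive and 6 negative log2 fold changes. After thinning to equal reads per nucleus the log2 fold change was 8.96. This says little about a difference in reads per nucleus, because CPM are already scaled by reads and so large a change could hardly vanish. Reads of Vwf in 84.8% and 89.0% of G14.5 nuclei are consistent with expression in hepatocytes in gestation, which stays a hypothesis found and tested on the same data. Vwf overlaps 0 other annotated genes.

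Globin genes and the median of the Kupffer cell and macrophage list (-1.134 at G0, -1.196 at G14.5 and -1.068 at P7L) lay lower in the perfusion libraries at every stage, although single macrophage markers such as C1qa at G0 lay higher. Whether RNA from other liver cells in the liver tissue preparation explains this stays open. Of 12 medians of the endothelial, stellate, cholangiocyte and B cell lists over the 3 stages, 10 were below 0, but of 21 shares of reads in the 7 lists other than hepatocyte, macrophage and erythroid only 11 were lower in perfusion. At G0, perfusion had more endothelial (0.005084% against 0.00375%) and stellate reads (0.003075% against 0.001722%), and mesothelial reads were higher in perfusion at all 3 stages. The median of the Kupffer cell list was -0.87 after thinning. This says little about a difference in reads per nucleus, because CPM are already scaled by reads. The levels are low, with macrophage markers at 0.00248% of reads or less in every library, and no biological explanation was tested. All 10 splits of the 6 libraries into 3 and 3, the real one included, called 0 genes by edgeR (highest other split 0), and 10 splits are too few for a share under 0.05.

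The preparations differed in opposite directions between stages in some measures, and none of these differences was tested. Perfusion minus liver tissue gave a zonation index difference of 0.011 at G0, -0.102 at G14.5 and -0.128 at P7L. The median log2 fold change of perfusion over liver tissue at G0, G14.5 and P7L was -0.076, 0.356 and 0.277 for fatty acid and triglyceride synthesis, and -0.091, 0.446 and 0.332 for gluconeogenesis and glycolysis. It was -0.004, 0.293 and 0.253 for amino acid catabolism and the urea cycle, and -0.027, 0.058 and 0.268 for the acute phase response. Periportal genes had -0.203, 0.272 and 0.454, and stellate and fibroblast markers 0.019, -0.802 and -0.732.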

How the results depend on the processing

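Scaling by library size alone and removal of a length trend were chosen after the data were seen. No called gene changed sign in any alternative, and of 99, 68 and 87 named genes 69, 3 and 64 kept their side of the threshold throughout, for G14.5 against G0, P7L against G0 and P7L against G14.5. In that order the gene counts were 1778, 426 and 1386 with RLE, 1762, 443 and 1437 with limma-voom, 2089, 631 and 1675 with thinned nuclei and 1871, 542 and 1367 without the length trend. Fold changes fell with gene length, at a Spearman correlation of -0.057, -0.199 and -0.153, and without this trend 936 genes were higher and 935 lower for G14.5 against G0, 265 and 277 for P7L against G0, and 658 and 709 for P7L against G14.5. With 1 library left out they ran from 661 to 1885, 46 to 609 and 450 to 2350, and those for the preparations from 0 to 0. With 1 library left, a stage is assumed to vary like the others. The genes called in the same direction in both comparisons with G0 numbered 35 to 338 with 1 library left out, and 2, 116 and 54 on the authors' values with pseudocounts of 1 and 0.1 and with filterByExpr alone. With 1 library left out the lists called numbered 12 to 15, 9 to 12, 11 to 13 and, for the preparations, 10 to 16. DESeq2 called 3429, 1901, 2631 and, for the preparations, 87 genes, and 947 in the same direction in both comparisons with G0. In the simulated data 85 of its 163 calls for G14.5 against G0 were false. Far fewer genes were changed there than edgeR called in the real data, so this share cannot be applied to the 3429 calls. On the authors' values the counts for G14.5 against G0 and P7L against G0 were 1128 and 4 with a pseudocount of 1, and 205 for P7L against G0 with 0.1. With filterByExpr alone P7L against G0 had 92 calls and with no filter 227, and the cause was not tested. An estimated correlation left 0 lists called in each comparison. Without the preparation term, which is also the replicate block, the counts were 2095, 578 and 1597. The removal of nuclei with over 1% of reads in other markers or under 1000 genes removed none, so those alternatives gave no value.

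At least 2 cycling genes gave shares of 5.49% and 2.76% at G0, for liver tissue and perfusion, 21.4% and 15.3% at G14.5 and 16.3% and 19.3% at P7L. All reads of each nucleus gave 2.78% and 5.43% at G0, 21.9% and 13.6% at G14.5 and 13.96% and 13.8% at P7L. Without the 4 leading genes the zonation index was 0.169 and 0.161 at G0, 0.199 and 0.1 at G14.5 and 0.164 and 0.076 at P7L, liver tissue first. In perfusion only the interval of P7L lay apart from that of G0. Small changes can be missed with these libraries: edgeR recovered 4.5% of simulated 1.5-fold changes for G14.5 against G0, where 2 libraries stand for each stage, and 15.2% for the preparations, with 3 libraries each.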

Other observations

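All tests in this part were chosen only after the results were seen.

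Among 204 families of genes with a shared symbol and at least 8 tested members, 7 of 1224 tests of enrichment (hypergeometric, Benjamini-Hochberg) passed an adjusted p of 0.05, in the families Serpina, Sult, Cyp and Slc. Of 14 Serpina genes, which encode serine protease inhibitors and hormone carriers, 8 were higher at G14.5 than at G0 (adjusted p = 0.000217) and 9 were lower at P7L than at G14.5 (adjusted p = 2.03e-06), Serpina6 and Serpina1e among them. Of 14 sulfotransferases (Sult), 6 were lower at G14.5 than at G0 (adjusted p = 0.00579) and 7 higher at P7L than at G14.5 (adjusted p = 0.000144). Cytochrome P450 genes (Cyp) had 18 of 83 lower at G14.5 (adjusted p = 3.48e-05) and 14 of 83 lower at P7L than at G0 (adjusted p = 6.63e-09), and solute carriers (Slc) had 35 of 282 higher at P7L than at G14.5 (adjusted p = 3.61e-06). Sult4a1 and Sult3a1 were called the other way in both comparisons. Most Cyp and Slc members were not called in these directions, and Cyp7a1 and Cyp8b1 were higher at G14.5 and P7L. Members of a family can share reads, and genes of a family are not independent.

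Neighbouring genes were called in the same direction more often than in permutations between genes of similar expression. For G14.5 against G0 there were 191 such pairs, and 1000 permutations gave 97.5 on average and 128 at most. Without pairs of one family there were 158 (at most 122 permuted). Families were set by symbol alone, which leaves related genes such as Fgg, Fga and Fgb, or F7 and F10, as different families. It also parts Gstm1 from the gene model Gm12498. Reads shared between copies were therefore not fully removed and stay open. Transcription running on into the next gene within 10 kb is argued against as the whole cause, with 94 of these pairs over 10 kb apart (at most 87 permuted). No biological explanation was tested. For P7L against G14.5 there were 148 pairs (at most 85 permuted), and for P7L against G0 17 (at most 14) but 8 of different families (at most 14).

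Runs of at least 3 neighbouring genes called in the same direction numbered 21 higher and 4 lower for G14.5 against G0, 5 higher and 16 lower for P7L against G14.5 and 2 lower for P7L against G0, and runs were not compared with permutations. Among the higher runs at G14.5, on chromosome 12 from 103450898 to 103863562 lay Ifi27l2b, Ppp4r4, Serpina10, Serpina6, Serpina1f, Serpina1b and Serpina1a. Sult4a1, Pnpla5 and Pnpla3 lay together on chromosome 15 from 84076097 to 84187236, Fads3, Fads2, Fads1 and Fen1 on chromosome 19, and the fibrinogen genes Fgg, Fga and Fgb on chromosome 3.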
